A study of Mus musculus with 27 samples.

How the data were processed

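Messenger RNA was measured by sequencing in 27 livers of ovariectomized female C57BL/6 mice, 3 for each of 9 groups: sesame oil vehicle and 8 doses of TCDD from 0.01 to 30 µg/kg, given by gavage every 4 days for 92 days, per the labels. One label also calls the dosing daily. RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols.

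The deposited values are whole read counts per gene. Per the submitters' processing notes, the authors checked reads with FastQC 0.11.2, trimmed them with cutadapt 1.4.1, aligned them to GRCm38 with TopHat 1.4.1, handled alignments with SAMtools 0.1.19 and counted reads per gene with HTSeq 0.6.1. The strand setting of the counting and the annotation release are not given in the sources used here. Each library has counts for 41388 gene identifiers and 5 summary lines, which were kept out of library sizes and tests. Reads on no gene made up 5.62% to 11.9% and reads on more than 1 gene 1.79% to 3.49% of these reads and the counted ones together. Alignments that were not unique were left out of these shares. They numbered 18007170 beside 26212424 counts in the first vehicle library and 32850334 beside 30873586 in the third 0.03 µg/kg library. Symbols were matched for 40254 identifiers and coordinates for 40340 in the GENCODE annotation of GRCm38.

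The total per library ranged from 434011 to 30873586 counts with a median of 19999504, and the library with the lowest total, the second at 0.3 µg/kg, was kept. Counts in no pair of libraries of a group matched more closely than separate samples would, with a chi-square per degree of freedom of at least 6.07. The names under which the counts were deposited carry 24 distinct index sequences. The vehicle to 0.1 µg/kg groups share a first set, the 0.3 to 10 µg/kg groups a second set, and the 30 µg/kg group reuses the 3 vehicle indices.

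Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups and its minimum of 10 counts, which left 15121, and libraries were scaled by TMM. A one-way quasi-likelihood model with robust dispersion was fitted to all 27 libraries, and each dose was compared with vehicle and 30 with 10 µg/kg. A second model took the rank of the dose, from 0 to 8, as a number. A further contrast set the 0.3 to 10 µg/kg groups against the rest, which runs with the index sets and also with dose. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Group means and SDs are of CPM with TMM scaling. The lowest dose of a gene is the lowest from which it was called with the same sign at every higher dose.

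Gene lists were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. There were 37 lists, 22 of pathways and 15 of cell type markers, of which 34 had the 4 measured members needed for a test. The comparisons, tests, thresholds, lists and the rule for named genes were set before the data were examined. The rule took every AhR battery member at every dose, the 10 largest rises and 10 largest falls at 30 µg/kg and 5 each at other doses, in the trend (by p) and between 30 and 10 µg/kg, among called genes with a mean of at least 1 CPM and no overlap between the groups, without predicted gene models, and up to 4 called and 2 uncalled members per list, with Ahr, Arnt and 3 reference genes. Some genes that the rule names are not reported here. Ngp, Saa1 and Acta1 in single libraries, the genes of daily rhythm in the closing part and the Krt19 values per liver were chosen after their values were seen.

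Where a group had no counts of a gene, the fold is a lower bound against 3 counts per library, and with 1 to 3 counts the ratio of pooled counts is given with an exact 95% interval. The overlap of exons with other genes was measured on the same annotation. Beside the genes with that limit in the report, Pkm shares 15.3% of its exonic bases with a gene of the same strand. On the other strand the share is 24.9% for Adrb3, 22.0% for Pklr and Ovol1, 19.0% for Bhlhe41, 18.0% for Dbp, 15.3% for Hamp2, 15.0% for Mpo, 12.5% for Ccna2, 11.5% for Mmp7 and 11.0% for Hmx1, and as the strand setting is not given their counts are uncertain to that extent.

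The test was tried on simulated counts for 15121 genes with 200 changed. For 30 µg/kg against vehicle it recovered 16.4% of 1.5-fold, 58.2% of 2-fold and 86.4% of 4-fold changes with 3.60% false calls, and for the trend 43.3%, 71.6% and 93.9% with 5.44% false calls. Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, other low-count filters, other thresholds, fits of 6 libraries alone, a block for the replicate number, non-robust dispersion, other dose scales, and leaving out each library, the shallow library or groups. Those that treat the 1 µg/kg libraries apart were added after the data were seen.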

Results

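RNA from the livers of ovariectomized female C57BL/6 mice was sequenced after repeated oral dosing with TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin), a persistent ligand of the aryl hydrocarbon receptor (AhR), or with the sesame oil vehicle. The mice were gavaged every 4 days for 92 days, and there were 9 groups of 3 livers: vehicle and 8 doses of TCDD from 0.01 to 30 µg/kg. The series title names dose-dependent metabolic reprogramming and fibrosis of the liver as its subject, and each dose was therefore compared with vehicle, the highest dose with the next one, and expression with the rank of the dose. The deposited values were whole read counts per gene and library. The total per library was 434011 counts in the second 0.3 µg/kg library and 11050391 to 30873586 counts in the other 26, and 15121 genes passed the low-count filter. Levels below are counts scaled to library size (CPM) as mean ± SD of 3 livers (n = 3), fold changes come from edgeR's quasi-likelihood fit, and p-values are Benjamini-Hochberg adjusted over the genes tested.

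The number of genes that differed from vehicle rose from 0 at 0.01 µg/kg to 5660 at 30 µg/kg (edgeR, adjusted p below 0.05). It was 6 at 0.03, 29 at 0.1, 179 at 0.3, 2927 at 1, 1520 at 3 and 3402 at 10 µg/kg. The 0.3 to 10 µg/kg libraries carry the second set of indices and the vehicle libraries the first. Dose and index set therefore cannot be told apart where these doses are compared with vehicle. Along the first principal component of the 26 deeper libraries, which held 59.3% of the variance among the most variable genes, the vehicle livers lay between -38.0 and -32.7 and the 30 µg/kg livers between 59.4 and 75.4.

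**Figure D1:**
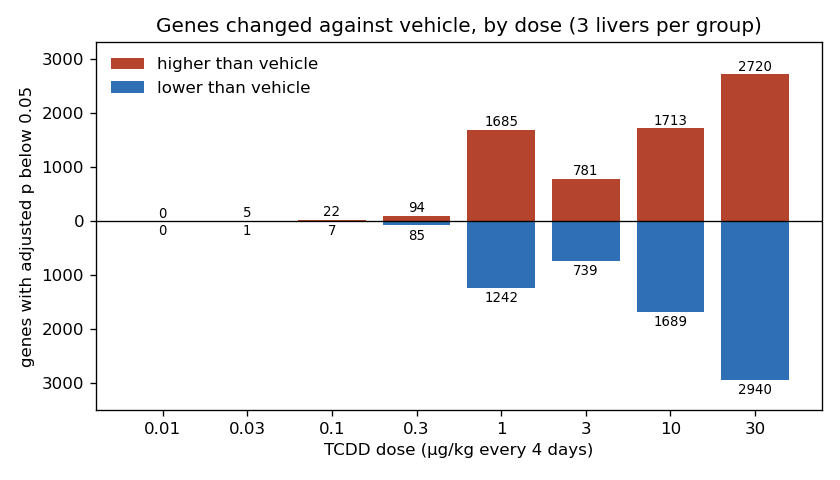
Bars give the number of genes higher (red, upward) or lower (blue, downward) than vehicle at an adjusted p below 0.05, for each TCDD dose in µg/kg on the horizontal axis, with 3 livers per group. The count rises from 0 at 0.01 µg/kg to 2720 higher and 2940 lower genes at 30 µg/kg, and the 1 µg/kg group, with 1685 higher and 1242 lower, stands above the 3 µg/kg group, with 781 and 739.

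Cyp1a1, the cytochrome P450 gene whose transcription is the classic readout of the AhR, had the largest called rise at 0.03, 0.1 and 0.3 µg/kg. It averaged 3.12 ± 0.605 CPM in vehicle livers and 147 ± 28.9 CPM at 0.03 µg/kg, a log2 fold change of 5.55 (SE 0.27, adjusted p = 3e-13), and reached 1234 ± 102 CPM at 0.1 µg/kg and 3064 ± 816 CPM at 0.3 µg/kg. Its neighbour Cyp1a2, a caffeine- and estrogen-oxidizing P450, stood at 728 ± 57.9 CPM in vehicle livers and was 4.54-fold higher at 0.03 µg/kg (adjusted p = 3.69e-06), 8.21-fold higher at 0.1 µg/kg and 14.7-fold higher at 0.3 µg/kg. In the GRCm38 annotation Cyp1a1 (ENSMUSG00000032315) lies on chromosome 9 from 57687928 to 57703824 on the plus strand, and Cyp1a2 (ENSMUSG00000032310) from 57676937 to 57683703 on the minus strand.

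At 0.01 µg/kg no gene passed the threshold in edgeR, 724 genes had an unadjusted p below 0.05, and DESeq2 called 15 genes. Without the first 0.01 µg/kg library the edgeR count was 56. Cyp1a1 measured 3.62 ± 0.933 CPM and Cyp1a2 1452 ± 262 CPM at this dose, and the Cyp1a2 fold of 1.99 had an adjusted p of 0.193 in edgeR and 0.00429 in DESeq2.

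The 6 genes at 0.03 µg/kg were Cyp1a1, Cyp1a2, Dbp, Nr1d1 and Nr1d2, which rose, and Loxl4, which fell. Dbp, a transcription factor under direct control of the circadian clock, went from 1.10 ± 0.164 to 13.2 ± 6.59 CPM (11.9-fold, adjusted p = 0.00123), and Nr1d1, which encodes the clock repressor REV-ERBα, was 3.35-fold higher (adjusted p = 0.000378). Loxl4, a lysyl oxidase family gene for collagen crosslinking, fell 3.98-fold from 23.3 ± 4.66 to 5.83 ± 1.90 CPM (adjusted p = 0.000399). The Dbp call was lost in a fit of the 6 libraries alone (adjusted p = 0.0847), and that of Nr1d2 without the first or without the third vehicle library (0.086 and 0.117). At 0.1 µg/kg 22 genes were higher and 7 lower: Bhlhe41 was 11.5-fold and Per3, a period gene, 9.51-fold higher, while Npas2, a partner of the clock activator BMAL1, was 7.63-fold lower (adjusted p = 0.00427, and 0.0766 without the third 0.1 µg/kg library). Nqo1, the quinone reductase, was 1.84-fold higher (adjusted p = 0.0427), a call lost when any of the 6 libraries compared was left out (adjusted p from 0.0995 to 0.253). DESeq2 called 58 genes at 0.1 µg/kg and a fit of the 6 libraries alone called 77. The hour at which each liver was collected is not given in the labels used here, and genes with a daily rhythm made up a part of the low-dose calls.

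At 0.3 µg/kg 94 genes were higher and 85 lower. Ahrr, which encodes the repressor of the AhR, entered at 4.91 ± 3.32 against 0.150 ± 0.0648 CPM (log2 fold change 4.33, SE 0.39, adjusted p = 9.07e-08), and the neuronal pentraxin gene Nptx1 was 35.6-fold higher (adjusted p = 9.63e-09). Slc34a2, a phosphate transporter gene, fell 12.5-fold (adjusted p = 0.0085), and Arntl, which encodes BMAL1, fell 8.30-fold (adjusted p = 0.00779). Both falls, and that of Srgap3 (4.13-fold), missed the threshold without the third 0.3 µg/kg library, with adjusted p of 0.175, 0.14 and 0.125. The count of genes was 53 without that library, 109 without the first and 104 without the third vehicle library. The count was 280 in DESeq2 and 106 in a fit of the 6 libraries alone, and the second library of the group held 434011 counts.

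Of the 10 measured members of the AhR target battery, a list fixed before the data were examined, 0 were called by edgeR at 0.01 µg/kg, 2 at 0.03, 3 at 0.1, 5 at 0.3, 8 at 1 and 3, and 9 at 10 and 30 µg/kg, all of them higher. At 0.3 µg/kg Cyp1b1 (adjusted p = 0.422) and Nqo1 (0.0694) lost their calls without the third library of the group, and Cyp1b1 also without any 1 of the vehicle libraries (adjusted p from 0.0795 to 0.136) and in a fit of the 6 libraries alone (0.0802). The counts adjusted over the list alone were 1, 3, 5, 7, 9, 9, 10 and 9. The list passed camera's competitive test at every dose from 0.03 µg/kg upward, with the preset correlation (adjusted p = 2.21e-27 at 0.03 and 9.79e-44 at 30 µg/kg) and also with an estimated correlation (adjusted p = 4.48e-05 and 1.5e-06). Members differed in the dose at which they rose. Tiparp, a mono-ADP-ribosyltransferase gene, was first called at 1 µg/kg, 3.27-fold higher, and reached 21.8-fold at 30 µg/kg. Nfe2l2, which encodes the oxidative stress regulator NRF2, was 1.78-fold higher at 1 µg/kg (adjusted p = 0.000586) and 3.95-fold higher at 30 µg/kg. Cyp1b1 was at 0.763 ± 0.0718 CPM in vehicle livers, had a log2 fold change of 7.51 at 1 µg/kg (SE 0.34, adjusted p = 3.44e-14) and reached 1964 ± 636 CPM at 30 µg/kg. Ugt1a6b was not called by edgeR with TMM scaling at any dose, with 32.4 ± 6.14 CPM at 30 µg/kg against 24.4 ± 2.11 CPM. It passed at 30 µg/kg with RLE (adjusted p = 0.0478) and upper-quartile factors (0.0483) and at 10 µg/kg in a fit of the 6 libraries alone (0.0205). It shares 60.6% of its exonic bases on the same strand with other Ugt1a genes, so its counts and those of Ugt1a6a are uncertain.

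**Figure D2:**
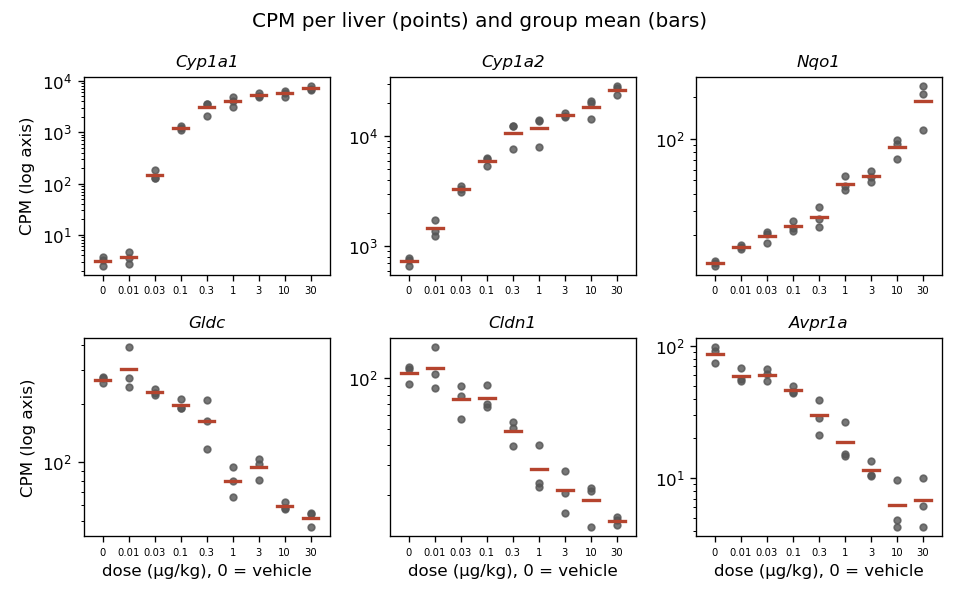
Each point is the CPM of 1 liver on a log axis against the TCDD dose in µg/kg (0 is vehicle), and bars mark group means, for 3 genes that rose (Cyp1a1, Cyp1a2, Nqo1) and 3 that fell (Gldc, Cldn1, Avpr1a). Cyp1a1 goes from a mean of 3.12 CPM in vehicle livers to 7201 CPM at 30 µg/kg, and Gldc from 267 to 51.7 CPM.

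At 1 µg/kg 1685 genes were higher and 1242 lower. Of the calls, 57.6% were higher with TMM scaling, 66.7% with RLE factors and 65.2% in DESeq2. The largest rises were in granule genes of maturing neutrophils: Ltf (lactoferrin), Ngp, Camp and Mpo (myeloperoxidase) rose together with Cyp1a1, which was at 4018 ± 846 CPM. The group held unlike livers, with Ngp at 253 CPM in the first, 0.607 in the second and 25.5 in the third library, against at most 0.0803 CPM in a vehicle liver. Vehicle livers held 1 count of Ltf and 3 of Ngp in all, which gave ratios of pooled counts of 2660 (95% exact interval from 477 to 105000) and 1770 (605 to 8590). All 8 neutrophil markers tested rose (adjusted p = 1.55e-05 by camera, 0.314 with an estimated correlation), as did 10 of 12 markers of recruited macrophages and monocytes, 7 of 9 Kupffer cell markers, 14 of 21 chemokine and cytokine genes and 13 of 19 cell cycle genes. With the estimated correlation each of these had an adjusted p between 0.314 and 0.361. Among genes that fell were Slco1a1, an organic anion transporter, 17.6-fold lower (adjusted p = 0.00302), and Npas2, 81.3-fold lower. With the second 1 µg/kg library as the only one of its group, assumed to vary like the libraries of the other groups, an alternative chosen after the data were seen, 497 genes were called, and neither Ltf, Ngp, Camp, Mpo nor Slco1a1 was among them. Slco1a1 kept a log2 fold change of -3.61 there (adjusted p = 0.22), while Ngp had 3.67 and Camp 1.74. The Ngp call was also lost in a fit of the 6 libraries alone (adjusted p = 0.0837). The count was 1731 without the first 1 µg/kg library, 1863 without the third vehicle library and 1591 in a fit of the 6 libraries alone.

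At 3 µg/kg 781 genes were higher and 739 lower, among them Cyp1a1 at 5261 ± 509 CPM and Cyp1b1 at 222 ± 26.2 CPM. Pnliprp1, a lipase-related gene of the pancreas, and the epithelial transcription factor gene Ovol1 had no counts in vehicle livers and were at least 56.4-fold and 51.6-fold higher, against a floor of 3 counts per library. The falls included Serpina7, the thyroxine-binding globulin gene, 30.5-fold lower (adjusted p = 6.98e-05), and Serpina1e, 30.2-fold lower (adjusted p = 0.00457). Of the lists, 7 of 22 fatty acid oxidation genes fell and 0 rose (camera adjusted p = 0.00356, and adjusted p = 0.766 with an estimated correlation), and 4 of 17 NRF2 and glutathione genes rose (adjusted p = 0.00026, and 0.766 with an estimated correlation). Of the 8 neutrophil markers 0 were called by edgeR at 3 µg/kg. The count of genes was 917 without the third vehicle library, 1000 without the second and 949 without the third 3 µg/kg library. A fit of the 6 libraries alone called 1996 genes, more than the 1591 of such a fit at 1 µg/kg.

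At 10 µg/kg 1713 genes were higher and 1689 lower. Col9a2, a collagen IX chain gene normally active in cartilage, rose to 193 ± 60.4 CPM from 0.0442 ± 0.0407 CPM (ratio of pooled counts 4410, exact interval 1510 to 21400), and Pnliprp1 to 47.0 ± 28.3 CPM. Hao1, the peroxisomal glycolate oxidase gene of hepatocytes, fell to 0.0731 ± 0.0655 CPM from 160 ± 42.2 CPM, a 2190-fold difference (adjusted p = 6.49e-15). Of the fatty acid and triglyceride synthesis genes 10 of 19 fell and 1 rose (adjusted p = 2.32e-05, and 0.222 with an estimated correlation), 9 of 17 one-carbon and methionine genes fell (1.15e-05, and adjusted p = 0.222 with an estimated correlation), and 10 of 21 matrix remodelling genes rose (adjusted p = 4.74e-07, and 0.222 with an estimated correlation). Of the cell cycle genes 12 of 19 rose, and of the neutrophil markers 5 of 8 (adjusted p = 0.498 for both with an estimated correlation). Higher genes were 50.4% of the calls with TMM scaling, 61.6% with RLE size factors (2019 of 3278), 62.2% with upper-quartile factors (2035 of 3273) and 60.4% in DESeq2 (1939 of 3211). Without the third vehicle library 2162 genes were called.

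At 30 µg/kg the liver differed from vehicle in 5660 genes, 2720 higher and 2940 lower, which is 37.4% of the genes tested. The called genes included members of the drug, lipid, bile acid and amino acid metabolism, matrix and inflammatory lists. As lists, only the AhR target battery, 1 of 34, passed camera with an estimated correlation at this dose. Cyp1a1 reached 7201 ± 652 CPM, a log2 fold change of 11.17 (SE 0.33, adjusted p = 2.18e-18), and Cyp1a2 26410 ± 2400 CPM. Col9a2 (ENSMUSG00000028626, chromosome 4 from 121039385 to 121055322) rose to 410 ± 69.5 CPM from 0.0442 ± 0.0407 CPM, a ratio of pooled counts of 9830 (exact interval 3360 to 47700). Ecel1, Pnliprp1, Mmp7 (matrilysin), Tgm3 (an epidermal transglutaminase), Dmbt1 and the homeobox gene Hmx1 had no counts in vehicle livers and were at least 341, 210, 176, 157, 145 and 105-fold higher. Cdh22, also without counts in vehicle livers and at least 103-fold higher, was called by edgeR (adjusted p = 0.0125) and not by DESeq2 (adjusted p = 0.17). Hao1 (ENSMUSG00000027261, chromosome 2 from 134497361 to 134554368) fell 2040-fold to 0.0676 ± 0.0635 CPM. The sulfotransferase gene Sult3a1 fell 825-fold from 172 ± 90.3 CPM and its close copy Sult3a2 at least 94.3-fold, and Slco1a1 went from 4450 counts to 2 in 3 livers, a ratio of 2160 (597 to 17800). Serpina1e fell 103-fold, Adgrf1 138-fold and Mmd2 127-fold. For Ube2u, the beta-3 adrenergic receptor gene Adrb3 and Dlgap1, with 1 to 3 counts left at 30 µg/kg, the ratios of pooled counts were 253 (45.0 to 10000), 158 (53.6 to 767) and 108 (18.9 to 4290). These intervals and the floors cover counting error only.

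Higher genes were 48.1% of the calls at 30 µg/kg with TMM scaling, 59.3% with RLE size factors (3345 of 5644), 59.4% with upper-quartile factors (3351 of 5644) and 58.4% in DESeq2 (3170 of 5429). RLE factors moved the median log2 fold change of all genes from -0.01 to 0.10, a shift of 0.11. Changes near that size depend on the scaling. Some calls on larger changes, such as that of Clec4f (below), also turned with it. Of the 5660 calls, 5019 were made in the same direction with RLE factors. The labels give no measure of total RNA per liver.

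Genes against oxidative stress rose as a group at 30 µg/kg. All 17 tested members of the NRF2 and glutathione list were higher (camera adjusted p = 8.66e-12), and with an estimated correlation the adjusted p was 0.0646. Ugdh, which makes UDP-glucuronate for conjugation, was 7.12-fold higher at 928 ± 148 CPM, Srxn1 (sulfiredoxin) 10.2-fold, the glutathione transferase gene Gstm3 31.7-fold and the efflux pump gene Abcc4 35.4-fold (adjusted p from 1.52e-10 to 8.12e-07). Of the pentose phosphate and NADPH genes 5 rose and 1 fell among 11, with Pgd 3.49-fold higher (adjusted p = 2.74e-06), and the list did not pass (camera adjusted p = 0.053). Without the first vehicle library, or without the first 30 µg/kg library, 3 of these genes were called, all of them higher. Heme and iron genes went both ways, with 2 higher and 6 lower of 17 (adjusted p = 0.12): Hamp, the gene of the iron hormone hepcidin, fell 6.56-fold to 193 ± 56.2 CPM and Hamp2 32.1-fold.

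Bile acid genes were lower at 30 µg/kg, as were hepatocyte markers (below). Of 16 synthesis genes 12 fell and 0 rose (camera adjusted p = 1.1e-05, and 0.114 with an estimated correlation). Hsd3b7, an early enzyme of bile acid synthesis, fell 2.97-fold to 321 ± 37.9 CPM, Cyp2c70, which hydroxylates murine bile acids, 4.20-fold, and Baat, the conjugating enzyme, 2.34-fold. Hsd3b7 shares 62.0% of its exonic bases with an overlapping gene of the same strand. Of 14 transporter genes 8 fell and 1 rose (adjusted p = 0.0368, and adjusted p = 0.284 with an estimated correlation). Slc10a1, the main bile acid uptake transporter, fell 2.95-fold from 729 ± 31.2 CPM, and the gene that rose was Abcc4. Abcc2 stood at 681 ± 55.0 against 599 ± 12.9 CPM (adjusted p = 0.411).

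Lipid genes fell in synthesis and in oxidation alike, as did hepatocyte markers (below). Of 19 fatty acid and triglyceride synthesis genes 12 fell and 1 rose (adjusted p = 8.67e-07, and 0.0986 with an estimated correlation), with the desaturase genes Fads1 7.30-fold and Fads2 4.98-fold lower and Agpat2 5.41-fold lower. Of 22 fatty acid oxidation genes 12 fell and 0 rose (adjusted p = 0.000986, and 0.362 with an estimated correlation), with Acsl1 3.25-fold lower. Of 21 cholesterol synthesis genes 14 fell and 0 rose (adjusted p = 2.36e-05, and 0.298 with an estimated correlation), with Sc5d 3.54-fold and Srebf2, a master regulator of the pathway, 2.47-fold lower; 9 members were called without the first or without the third 30 µg/kg library. Genes of lipid uptake, droplets and export were split, with 7 higher and 5 lower of 17 (adjusted p = 0.526): the fatty acid uptake gene Cd36 rose to 534 ± 182 CPM (log2 fold change 3.17, SE 0.27) and Lpl 7.50-fold, and Apoa1 fell 7.34-fold from 12120 ± 3480 CPM.

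Members of the carbohydrate and amino acid lists were also called at 30 µg/kg. Camera with the preset correlation passed the one-carbon and urea cycle lists and not the other lists of this paragraph. In glycolysis 3 genes rose and 7 fell of 20 (adjusted p = 0.309), with the liver pyruvate kinase gene Pklr 8.25-fold lower at 30.4 ± 10.3 CPM and Pkm, the isoform gene of dividing and nonhepatic cells, 4.85-fold higher at 42.3 ± 4.26 CPM. In gluconeogenesis and glycogen metabolism 2 rose and 7 fell of 15 (adjusted p = 0.12), with the glycogen-targeting gene Ppp1r3b 5.07-fold lower. One-carbon and methionine genes fell, 13 of 17 with 0 higher (adjusted p = 6.68e-09, and 0.0646 with an estimated correlation): the glycine decarboxylase gene Gldc was 5.16-fold, the S-adenosylmethionine synthase gene Mat1a 3.99-fold and Shmt1 4.41-fold lower. Urea cycle genes fell, 6 of 8 with 0 higher (adjusted p = 0.00271, and 0.298 with an estimated correlation), with Otc 4.08-fold and Cps1 3.30-fold lower, while Arg1 stood at 1279 ± 44.3 against 1165 ± 62.6 CPM (adjusted p = 0.603). In the glutamine, proline and serine list 3 rose and 6 fell of 15 (adjusted p = 0.306); its median of 0.02 and mean of 0.09 were positive while camera's direction was down.

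Matrix genes were higher at 30 µg/kg. Of 25 collagen and matrix genes 16 rose and 1 fell (adjusted p = 9.17e-05, and 0.298 with an estimated correlation), with the tenascin gene Tnc 21.4-fold, Col1a2 4.12-fold and Col1a1, a main fibrillar collagen gene, 7.69-fold higher at 89.1 ± 52.7 CPM, and Fn1 (fibronectin, which hepatocytes also secrete into plasma) 2.33-fold lower. Of 21 matrix remodelling and TGF-beta genes 17 rose and 0 fell (adjusted p = 2.38e-08, and 0.114 with an estimated correlation), with Tgfb2 62.4-fold and the protease genes Mmp12 and Mmp13 72.1-fold and 69.1-fold higher. Of 21 chemokine and cytokine genes 11 rose and 2 fell (adjusted p = 0.0135, and 0.362 with an estimated correlation), with Ccl4 6.70-fold higher and Il18 2.63-fold lower, and 6 were higher and 1 lower without the third 30 µg/kg library. Of 19 cell cycle genes 15 rose and 1 fell (adjusted p = 0.000364, and 0.329 with an estimated correlation), with Ccne1 13.5-fold and Ccna2 5.09-fold higher, at 2.39 ± 0.623 and 4.80 ± 1.61 CPM.

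Markers of other cell types moved with these groups by unequal amounts. Of 9 cholangiocyte markers 8 rose (adjusted p = 3.58e-05, and 0.138 with an estimated correlation), with Prom1 21.8-fold and Krt19 11.4-fold higher, Krt19 being at 14.7, 3.96 and 17.1 CPM in the 3 livers. All 8 neutrophil markers rose (adjusted p = 0.000986, and 0.298 with an estimated correlation), with S100a8 41.5-fold higher. Of 12 recruited macrophage and monocyte markers 6 rose and 0 fell (adjusted p = 0.00163, and 0.298 with an estimated correlation), with Gpnmb 767-fold higher, and of 9 B and plasma cell markers 6 rose and 0 fell (adjusted p = 0.00271, and 0.298 with an estimated correlation). Of 13 stellate cell and myofibroblast markers, a list that shares collagen genes with the matrix list, 6 rose and 1 fell (adjusted p = 0.0165, and 0.298 with an estimated correlation). Kupffer cell (0 higher and 1 lower of 9, adjusted p = 0.795), sinusoidal endothelial (0 and 1 of 10, adjusted p = 0.884), T and NK cell (2 and 0 of 11, adjusted p = 0.292) and erythroid markers (0 and 0 of 5, adjusted p = 0.491) did not pass. With RLE and upper-quartile factors 1 sinusoidal endothelial marker rose and 1 fell, and in DESeq2 2 Kupffer cell markers rose and 1 fell. Without the second 30 µg/kg library 4 Kupffer cell and 2 endothelial markers were lower and 0 higher, without the first or without the third 0 Kupffer cell markers were called, and a fit of the 6 libraries alone had 2 Kupffer cell markers higher and 0 lower. Clec4f, the Kupffer cell lectin gene, was 1.79-fold lower (adjusted p = 0.0266), a call lost with RLE size factors (adjusted p = 0.051) and upper-quartile factors (0.0541), and without the first (0.166) or the third (0.167) 30 µg/kg library.

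**Figure D3:**
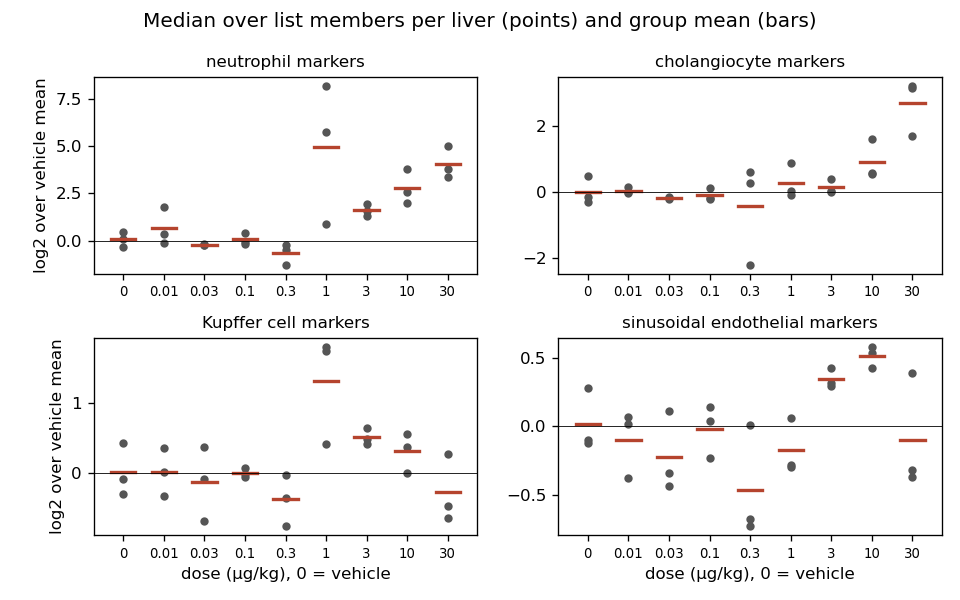
Each point is 1 liver and gives the median over a marker list of log2 CPM minus the vehicle mean, against the TCDD dose in µg/kg (0 is vehicle); bars mark group means, for neutrophil, cholangiocyte, Kupffer cell and sinusoidal endothelial markers. Neutrophil markers stand at 8.18 and 5.77 in the first and the third 1 µg/kg livers and between 3.35 and 5.02 at 30 µg/kg, while sinusoidal endothelial markers stay between -0.37 and 0.39 at 30 µg/kg.

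Hepatocyte genes fell at 30 µg/kg, 8 of 10 with 0 higher (adjusted p = 0.000223, and 0.114 with an estimated correlation), with Ahsg 3.08-fold lower at 3955 ± 955 CPM, while the hepatocyte regulator Hnf4a stood at 567 ± 81.6 against 650 ± 38.5 CPM (adjusted p = 0.421). The median over the hepatocyte markers, log2 over the vehicle mean, was -1.27, -0.65 and -1.38 in the 3 livers. Whether the bile acid, lipid, one-carbon and urea cycle genes fell beyond the hepatocyte markers was not tested. Periportal hepatocyte markers fell, 6 of 8 with 0 higher (adjusted p = 0.00653, and 0.298 with an estimated correlation), with Hal, the histidine ammonia-lyase gene, 5.67-fold lower; 4 were called without the first and 3 without the third 30 µg/kg library. Pericentral markers went both ways, 2 higher and 2 lower of 8 (adjusted p = 0.289), with Cyp1a2, itself an AhR target, 36.3-fold higher and Rgn 2.90-fold lower. The 3 lists with under 4 measured members had no list test. Adipocyte markers had 0 higher and 2 lower of 2, acinar markers 1 and 2 of 3, and muscle markers 0 and 1 of 3. The 2 adipocyte markers were Car3 and Adrb3, while Adipoq, Lep, Plin1, Cfd and Retn were not among the genes tested. Their falls are therefore not read as a change in adipocytes. The muscle gene that fell, Mylpf, lost its call without the third vehicle library (adjusted p = 0.471), in which Acta1 was at 46.4 CPM against at most 0.0523 CPM in the other vehicle livers. Without that library Acta1 was called higher (log2 fold change 9.18, adjusted p = 0.000125) and the muscle result turned to 1 higher and 0 lower, so its direction rests on 1 vehicle liver.

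Sex-dependent liver genes and other P450 genes went both ways at 30 µg/kg. Of 15 female-predominant genes 2 rose and 9 fell (adjusted p = 0.00347, and 0.298 with an estimated correlation), with Cyp17a1 19.9-fold lower at 4.64 ± 1.67 CPM. Of 15 male-predominant genes 4 rose and 6 fell (adjusted p = 0.495; the median of 0.43 was positive and the mean of -1.53 negative), with Cyp2d9 9.76-fold higher and Mup3, a major urinary protein gene, 52.0-fold lower. Of 16 other P450 genes 2 rose and 8 fell (adjusted p = 0.0307, and 0.442 with an estimated correlation), with Cyp2a5 12.8-fold higher and Cyp4f14 11.4-fold lower. The Cyp2b, Cyp2c, Cyp2d, Mup, Sult3a and Serpina1 families hold near-identical copies, and their single-gene values are uncertain where reads fit more than 1 member. Ahr itself stood at 53.5 ± 8.86 against 48.2 ± 10.4 CPM (adjusted p = 0.577). Arnt was 1.31-fold lower (adjusted p = 0.0216), a call lost with RLE factors (adjusted p = 0.101), upper-quartile factors (0.0825) and DESeq2 (0.106), and without the first 30 µg/kg library (0.189). Of the reference genes, Hprt was 2.04-fold higher (adjusted p = 8.17e-06), Gapdh 1.19-fold (adjusted p = 0.596), and Actb 1.54-fold (adjusted p = 0.0841), which passed with RLE factors (adjusted p = 0.0422), upper-quartile factors (0.0376) and DESeq2 (0.0281).

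**Figure D4:**
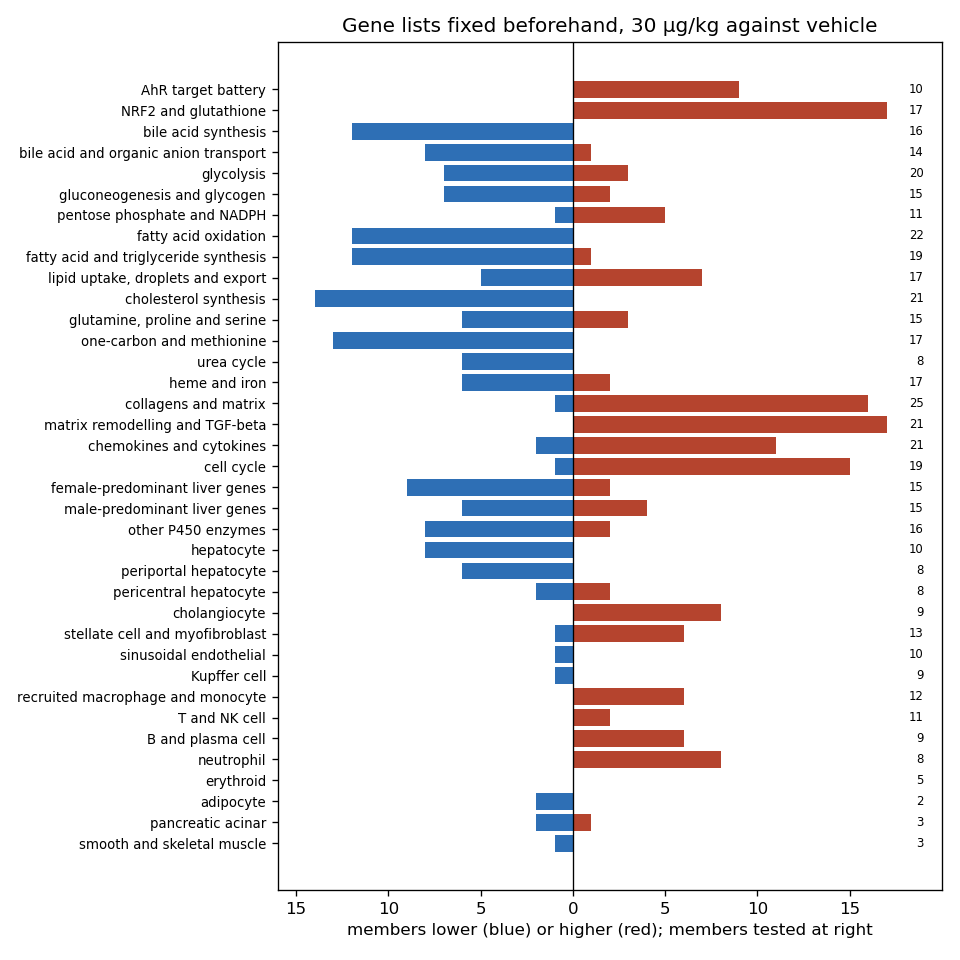
Bars count the members of each gene list fixed beforehand that were lower (blue, left) or higher (red, right) than vehicle at 30 µg/kg with an adjusted p below 0.05, and the number at the right edge is the count of members tested. All 17 NRF2 and glutathione genes are higher, and 13 of 17 one-carbon and methionine genes are lower.

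Across the lists, 22 of 34 passed camera with the preset correlation at 30 µg/kg, 1 (the AhR target battery) with an estimated correlation, and 28 by fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. The preset correlation also passed 5 of 34 lists at 0.01 µg/kg, where edgeR called 0 genes, and 12 at 0.03 µg/kg, where it called 6. With an estimated correlation 0 and 2 lists passed at those doses, so a small preset p-value alone is weak evidence for a list. Adjusted over the list alone, 9 AhR battery genes, 17 NRF2 and glutathione genes, 13 bile acid synthesis genes, 13 fatty acid oxidation genes, 14 cholesterol synthesis genes, 14 one-carbon genes and 9 B and plasma cell genes were called.

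The livers at 30 µg/kg differed from those at 10 µg/kg in 484 genes, 208 higher and 276 lower. The 10 µg/kg libraries carry the second set of indices and the 30 µg/kg libraries the vehicle indices. Dose and index set therefore cannot be told apart in this comparison. Tgm3 rose further to 19.9 ± 12.3 CPM (33.6-fold, adjusted p = 0.000437), Dmbt1 38.2-fold, Slc7a11, the cystine transporter gene of glutathione supply, 27.6-fold, the growth factor gene Ereg 17.4-fold, and the acute phase gene Orm3 12.9-fold (adjusted p = 0.0478). Cyp2c38 fell from 63.8 ± 30.5 to 7.03 ± 5.72 CPM (9.03-fold, adjusted p = 0.00158), Cyp2c69 10.0-fold, Cyp3a44 9.99-fold, Adgrf1 13.8-fold and Gpx6 8.40-fold (adjusted p = 0.0174 to 0.0455). The count was 46 without the first and 144 without the second 10 µg/kg library, and 65, 1741 and 57 without the first, the second and the third 30 µg/kg library. A fit of the 6 libraries alone called 2 genes, and the genes named here that it tested had adjusted p from 0.0794 to 0.183. Tgm3, Dmbt1, Ereg and Cyp2c38 kept their calls with any 1 of the 6 libraries left out, and the other genes named here did not.

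Along the rank of the dose over all 27 livers, 7039 genes had a trend, 3521 rising and 3518 falling. Among the rising genes with the smallest p-values were Ism2, which went from 0.249 ± 0.0453 CPM in vehicle livers to 21.5 ± 1.70 CPM at 30 µg/kg (log2 slope per dose step 0.95, SE 0.04, adjusted p = 2.36e-16), Col9a2 (slope 2.83), the phosphomannomutase gene Pmm1 (0.45), Cdh18 (0.71) and the replication licensing inhibitor gene Gmnn (0.39). Among the falling ones were the tight junction gene Cldn1, from 108 ± 13.3 to 14.0 ± 0.829 CPM (slope -0.42, SE 0.03, adjusted p = 3.27e-13), Stra6l, a retinol-binding protein receptor gene of the liver (-0.22), the vasopressin receptor gene Avpr1a (-0.51), Gldc (-0.34) and Loxl4 (-0.63). Rising genes were 50.0% of the trends with TMM, 61.6% with RLE factors (4241 of 6886), 61.8% with upper-quartile factors (4243 of 6865) and 60.6% in DESeq2 (4376 of 7222). Without the 10 and 30 µg/kg groups 3550 genes had a trend.

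Of the genes called at 30 µg/kg, 2934 were also called at 10 µg/kg in the same direction and 0 in the opposite one. Lists drawn independently would share 308 higher and 328 lower genes. Simulated groups without any effect, set against the same vehicle libraries, shared 0 genes in 20 draws. They were drawn around the mean of those vehicle livers, so they could not show overlap that comes from the sampling of these livers. Splitting 3 controls leaves too few libraries per part, so the part of the overlap that comes from the shared vehicle livers was not measured. The lowest dose from which a gene was called at every higher dose was 0.03 µg/kg for 6 genes, 0.1 for 21, 0.3 for 117, 1 for 713, 3 for 270, 10 for 1807 and 30 for 2726. Counted by the first call at any dose, sustained or not, genes numbered 6 at 0.03, 23 at 0.1 and 151 at 0.3 µg/kg. They numbered 2760 at 1, 453 at 3, 1345 at 10 and 2191 at 30 µg/kg. Without the third vehicle library 1921 genes, not 2934, were shared by 10 and 30 µg/kg. Among neighbours at lower doses, 28 genes were shared by 0.1 and 0.3 µg/kg, 167 by 0.3 and 1, 1061 by 1 and 3, and 1297 by 3 and 10 µg/kg.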

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

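The test in this part was chosen after the result was seen. The summary lines of the counting, which no comparison used, differed between groups. Reads that fell on more than 1 gene made up 3.11% (SD 0.127, n = 3) at 30 µg/kg against 2.04% (SD 0.107, n = 3) in vehicle livers. Both shares leave out alignments that were not unique. The exact two-sided permutation p was 0.1, the smallest that the 20 arrangements of 3 against 3 livers allow.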

How the results depend on the processing

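The alternatives that treat the 1 µg/kg libraries apart were chosen after the data were seen, and the others were planned. Of 345 values of named genes 58 changed their call under some alternative and 0 that were called with either setting reversed their direction, while some uncalled ones changed sign; over all alternatives 138 calls were lost and 72 gained. The balance of the calls at 30 µg/kg turned from 48.1% higher with TMM to 59.3% with RLE factors. At 0.3, 1 and 3 µg/kg it went from 52.5%, 57.6% and 51.4% to 58.8%, 66.7% and 58.6%. The causes of the differences were not tested. DESeq2 called 15 genes at 0.01 µg/kg, 58 at 0.1 and 280 at 0.3. Fits of 6 libraries alone called 77 at 0.1, 106 at 0.3, 1591 at 1, 1996 at 3 and 3904 at 10 µg/kg and 2 between 30 and 10 µg/kg, which turns the order of 1 and 3 µg/kg. An adjusted p below 0.01, a stricter threshold by construction, left 97 genes at 0.3, 1529 at 1, 824 at 3, 1883 at 10 µg/kg, 110 between 30 and 10 µg/kg, 1501 in the contrast of index sets and 1670 shared by 10 and 30 µg/kg; a 1.5-fold minimum left 1127 in the contrast of index sets. At 0.01 µg/kg 1 gene was called with no low-count filter, with 1 µg/kg by its second library alone, without the 1 µg/kg group, and without the shallow library and 2 libraries at 1 µg/kg. The second library alone gave 497 genes at 1 µg/kg, and leaving out the shallow library and 2 libraries at 1 µg/kg gave 540 there and 729 between 30 and 10 µg/kg. The trend had 3550 genes without the 10 and 30 µg/kg groups, 1 list passed with an estimated correlation at 30 µg/kg, and 6929 genes were called at any dose. Leaving out each library gave 0 to 56 genes at 0.01, 5 to 7 at 0.03, 20 to 29 at 0.1, 53 to 240 at 0.3, 1731 to 2990 at 1, 917 to 1225 at 3, 2162 to 2820 at 10 and 4170 to 5901 at 30 µg/kg, 46 to 1741 between 30 and 10 µg/kg, 1975 to 3064 for the index sets, 6293 to 7350 for the trend, 21 to 22 lists, and 1921 to 2856 genes shared by 10 and 30 µg/kg. The replicate numbers share no pairing: deviations of same-numbered libraries correlated at 0.01 on average over 108 pairs (-0.40 to 0.36), and 10 of 27 libraries matched their own number best. With the number as a block the counts were 0, 6, 32, 192, 2909, 1505, 3395 and 5638 from the lowest to the highest dose, 553 between 30 and 10 µg/kg, 2778 for the index sets, 6990 for the trend, 22 lists and 2920 shared genes. Without the library of 434011 counts 169 genes were called at 0.3 µg/kg, not 179, and what depth limits was not tested further.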

Other observations

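All tests of the 3 patterns weighed here were chosen after the result was seen; the counts over other splits of the libraries were planned. Genes with a daily rhythm moved across the dose series. Of 14 such genes 0 were called by edgeR at 0.01 µg/kg, 3 at 0.03, 8 at 0.1, 12 at 0.3, 14 at 1, 3 and 10, and 12 at 30 µg/kg. Arntl, which encodes the clock activator BMAL1, was at 32.2 ± 3.14 CPM in vehicle livers (n = 3), 1.04 CPM at 3 µg/kg and 4.40 CPM at 30 µg/kg. Dbp, a clock output gene, was at 1.10, 187 and 52.0 CPM in the same groups. Nr1d1 had its highest mean, 185 CPM, at 0.1 µg/kg, and Per2, a period gene, went from 2.59 to 50.0 CPM at 3 µg/kg.

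Between the 0.3 to 10 µg/kg groups and the rest, the contrast that runs with the index sets, 2871 genes differed, 1521 higher and 1350 lower. The split was 1731 and 1094 with RLE factors and 1821 and 1100 in DESeq2. The contrast sets higher doses against mostly lower ones, so genes that follow dose enter it and its count does not measure an index effect. Between 0.3 and 0.1 µg/kg, where the 2 sets meet, 3 genes differed, all higher, in a comparison outside the planned ones. Saa1, an acute phase gene, was at 4934 CPM in the first 1 µg/kg liver and at 1997 CPM in the third 30 µg/kg liver, against 31.9 CPM in the vehicle liver with the most.

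More genes were called at 1 than at 3 µg/kg in the fit of all 27 libraries, 2927 against 1520, but not in fits of 6 libraries alone, with 1591 against 1996. With a single 1 µg/kg library in the fit, assumed to vary like the libraries of the other groups, the count was 2372 for the first, 497 for the second and 1541 for the third, and at 3 µg/kg it was 387, 468 and 655, so that the first and the third livers may carry the excess of the full fit. A larger amount of blood left in the tissue was argued against by hemoglobin transcripts. They were at 158 and 69.6 CPM in those livers and from 64.7 to 227 CPM in vehicle livers. Hemoglobin does not measure the neutrophils that such blood held, so blood as their source was not tested. The index set was argued against by its 9 libraries at other doses, whose median neutrophil score was 1.58 on the log2 scale against 8.18 and 5.77. A difference between animals, in infection or response, stays open and was not tested.

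Genes of daily rhythm were called from 0.03 µg/kg upward. The index set was argued against by the 8 of them called at 0.1 µg/kg, whose libraries share the first set with vehicle. The textbook order of peak hours ran with the dose of the highest mean, with a Spearman rho of 0.84 across the 14 genes. These were chosen after their values were seen and are not independent, so that no p-value is given. Arntl, Npas2, Clock and Nfil3, placed first in that order, were called lower at 10 µg/kg and the others higher. Any cause of such a split would raise rho, so it cannot decide between causes. From 10 to 30 µg/kg all 14 moved back toward vehicle and 0 of these moves were called by edgeR as a reversal. An hour of collection that differed between dose groups and TCDD acting on the liver clock cannot be told apart, since the labels used here give no hour.

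Neutrophil and cholangiocyte markers were higher at 30 µg/kg, while 0 of 9 Kupffer cell and 0 of 10 sinusoidal endothelial markers were called higher in the main edgeR fit. Other edgeR fits differed: with RLE factors 1 endothelial marker was higher and 1 lower. A fit of the 6 libraries alone had 2 Kupffer cell markers higher and 0 lower, and without the second 30 µg/kg library 4 were lower and 0 higher. If a lower share of hepatocytes were the only cause, all would rise alike. The smallest gap of the cholangiocyte or neutrophil score over the sinusoidal endothelial score in a liver was 1.29 on the log2 scale. That lay under the widest range between livers of 1.67, so the test could not decide. Split by type after that value was seen, the neutrophil gap of 3.41 exceeded 1.67, which argues against that cause alone for the neutrophil markers. The smallest cholangiocyte gap of 1.29 lay under its range of 1.52, so that test could not decide either. In a further, looser test, added after these values were seen, the mean cholangiocyte gap was 2.79 (SD 1.29, n = 3). The lowest cholangiocyte score, 1.69, lay above the highest endothelial score, 0.39. As this test followed others that could not decide, no conclusion is drawn from it for the cholangiocyte markers. Whether the endothelial cells themselves changed was not tested. Pancreatic tissue was argued against by 2 counts of Prss1, Cpa1, Pnlip and Cel in the 3 livers beside 1977 counts of Pnliprp1. A change in the number or state of neutrophils and bile duct cells stays open as a hypothesis.

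For the trend, 1 of 100 random orders of the libraries, the real one, gave as many as 7039 genes and the highest other gave 152. A share of 1 in 100 is the smallest that these orders allow, and it makes chance unlikely. Random orders do not test what may run with dose, such as the index set or an hour of collection that differed between groups. For the comparisons of 3 against 3 livers the 10 splits are too few for a share under 0.05. The real count and the highest other were 0 and 3 at 0.01 µg/kg, where all 10 splits gave as many, 6 and 0 at 0.03, 29 and 0 at 0.1, 179 and 0 at 0.3, 2927 and 571 at 1, 1520 and 1 at 3, 3402 and 1 at 10, 5660 and 0 at 30, and 484 and 280 between 30 and 10 µg/kg.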
